A study of Mus musculus with 18 samples.

How the data were processed

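RNA levels were measured on 18 Agilent 2-colour mouse arrays, which gave 36 channels. The first 6 channels held Dnmt3ab-deficient induced pluripotent stem cells (iPSC) of 3 clones, named 8, A6 and B2, each read once in Cy5 beside mouse embryonic fibroblasts (MEF) and once in Cy3 beside V6.5 embryonic stem cells (ESC), a mouse ESC line. The other 12 arrays held 4 control iPSC lines, numbered 3 to 6, on 3 arrays each, with 1 of the same 3 deficient clones showing signs of differentiation in the partner channel. The control RNA was in Cy5 on 9 of these arrays and in Cy3 on 3. The labels state that cells had been grown on fibroblast feeders and moved off them before RNA was taken.

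Per the file headers, the scanner software (Agilent Feature Extraction) gave the mean spot intensity and local background of each dye, before any normalization. Per the file headers it also gave processed signal intensities, with background subtracted and dyes normalized, and their log10 ratio of Cy5 over Cy3. The deposited value table held a log2 ratio per probe and array. Its scale and direction were not stated, and they were read from the values: the slope against the signal ratio of the deficient over the other channel was 1.006 to 1.409, with correlations across probes of 0.635 to 0.999. The submitters' notes name limma without a version.

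The values reported here started from the mean spot signals and local backgrounds. In limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table) they were background-corrected with normexp (offset 50), loess-normalized within arrays and Aquantile-normalized between arrays. Aquantile sets the distribution of average signal equal on every array, so a change in the total RNA level of most genes cannot be seen. Of 45018 array features, 41174 non-control probes were read and 36965 were kept, those well above background in at least 0.5 of the channels of at least 1 kind of RNA. A gene was the brightest of its probes, which gave 25203 names tested, with 2 left out for a missing value of a cell line. Current symbols came by accession for 14972 names, by symbol for 2562 and by a unique synonym for 1474, and 6195 kept the name in the files. Probe positions are those of the files, on mouse build mm7, and were available for 24834 genes. Outlier spots were left out and made up at most 0.45% of an array.

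The cell line was the replicate. A separate-channel fit over all 36 channels, with 12 line-and-state terms, a dye term and an intra-spot correlation of 0.768, gave 1 log2 value per line and state. Deficient iPSC (3 lines) and the same clones with signs of differentiation (3 lines) were each compared with the 4 control lines by limma. The difference between the 2 states was tested over the 3 clones as pairs. Deficient iPSC against V6.5 ESC and against MEF came from a limma fit of the log ratios of all 18 arrays with a dye term, each contrast resting on 3 arrays. V6.5 ESC and MEF were single reference RNAs, each in 1 dye, so their own spread was not measured and the dye term rested on the arrays read on the other scan day. The SE of these contrasts pooled the spread of all 18 arrays, which reuse the same lines, and was not that of the 3 arrays alone. Tests were two-sided with Benjamini-Hochberg adjustment over all genes, and a gene was called at an adjusted p under 0.05. Errors are standard errors (SE) of the difference unless marked SD.

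Samples, comparisons, tests, alternatives, 20 gene lists and the rule for named genes were fixed before the data were examined. The rule took Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l, Pou5f1, Nanog and Sox2 in every comparison. It took the 6 largest rises and 6 largest falls among called genes whose lines did not overlap (4 and 4 for the reference RNAs), leaving out clone and accession names. It also took up to 2 called members of each list with the largest change; other list members are given as examples, chosen after their values were seen. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 20 lists. Genes were also tested by chromosome with camera.

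The arrays were read on 2 scan days: 6 arrays on 2 slides with the deficient iPSC and both reference RNAs, and 12 arrays on 3 slides with the control lines and the differentiating clones. Deficient and control iPSC therefore shared neither a slide nor a scan day, and the planned fit with slide as a fixed block could not be made. Between 69.69% and 78.87% of probes were well above background on the first day and between 75.58% and 92.55% on the second, with no saturated spots. The number of arrays and lines limits the precision.

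The pipeline was tested on simulated data of 20000 genes with the same design and a spread set by hand. In the 3 comparisons among iPSC it called 41.2% to 60.3% of changes of 0.5 log2 units, 94.7% to 97% of changes of 1, and 100% of changes of 2. False calls made up 5.71% to 6.57% of calls there. The simulation held no effect of slide or scan day, so this share does not cover such effects in the comparisons made across scan days. Against V6.5 ESC, 231 of 404 simulated calls were of genes that did not differ between the kinds of cell, because a single reference RNA carries its own deviation; without that deviation there was 1 such call in 175. Against MEF the numbers were 198 of 376 and 2 of 173. Alternatives covered background correction, normalization, filters, probe summary, dye term, threshold, replicate unit, blocks and leaving out each line.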

Results

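The data were 36 channels of 18 arrays: 6 channels of Dnmt3ab-deficient iPSC from 3 clones, 12 of the same clones with signs of differentiation, 12 of 4 control iPSC lines, 3 of MEF and 3 of V6.5 ESC. Dnmt3a and Dnmt3b are the enzymes that place DNA methylation on unmethylated sites. The series set out to compare RNA levels of iPSC lines deficient in both with those of control iPSC lines. Median net signal per channel ran from 122.9 to 264.4 on the first scan day and from 88.62 to 312.6 on the second. Across genes, which are not independent replicates, the correlation was 0.985 to 0.999 between control lines, 0.994 to 0.998 between deficient lines and 0.981 to 0.985 between the groups. Deficient lines correlated with V6.5 ESC at 0.993 to 0.994 and with MEF at 0.885 to 0.889. Differentiating clones correlated with control lines, read on the same scan day, at 0.984 to 0.994. With deficient lines and V6.5 ESC, read on the other day, they correlated at 0.98 to 0.988 and 0.979 to 0.985. Deficient and control lines were read on different days, and V6.5 ESC on the same arrays as deficient lines. These values therefore do not show which kinds of iPSC and ESC were most alike.

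Dnmt3a RNA was lower in the deficient iPSC than in the control lines, at 9.54 ± 0.483 against 11.02 ± 0.355 (mean log2 signal ± SD, n = 3 and 4 lines), a difference of -1.49 ± 0.273 (adjusted p = 0.00504). The value came from a probe on chromosome 12 at 3825243 to 3826024, and the other 2 Dnmt3a probes differed by -2.31 and -1.10. Dnmt3b (probe on chromosome 2 at 153428204 to 153428263) was at 13.08 ± 0.646 against 13.39 ± 0.701 (SD), a difference of -0.32 ± 0.449 that did not pass the test (adjusted p = 0.596). The sources do not say which part of either gene was deleted, so a probe outside that part cannot show the deletion. Dnmt3l, the catalytically inactive cofactor of both enzymes, was higher by 1.5 ± 0.206 (adjusted p = 0.0016), and Dnmt1, the maintenance methyltransferase, by 0.61 ± 0.0918 (adjusted p = 0.00221).

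The largest rises in the deficient iPSC (log2 difference ± SE, 3 against 4 lines) were Rhox2a at 3.74 ± 0.392, Dazl at 3.31 ± 0.518, Zscan4c at 3.11 ± 0.733, Hormad1 at 2.80 ± 0.544, Stra8 at 2.71 ± 0.804 and Ushbp1 at 2.67 ± 0.213. Dazl is an RNA-binding protein of germ cells, Hormad1 a protein of meiotic chromosomes and Stra8 a factor of meiotic entry. Rhox2a and Zscan4c belong to families of near-identical copies, so which copy the probe reads is uncertain. The largest falls were Krt8 at -3.06 ± 0.239, Slit3 at -2.68 ± 0.314, Krt18 at -2.66 ± 0.354, Arl4c at -2.57 ± 0.409, Krt19 at -2.50 ± 0.235 and Kif1a at -2.37 ± 0.176. Krt8, Krt18 and Krt19 are keratins of simple epithelia, Slit3 a secreted guidance factor and Kif1a a motor protein of axons. Adjusted p-values of these 12 genes ran from 0.000237 (Kif1a) to 0.0314 (Stra8).

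**Figure D1:**
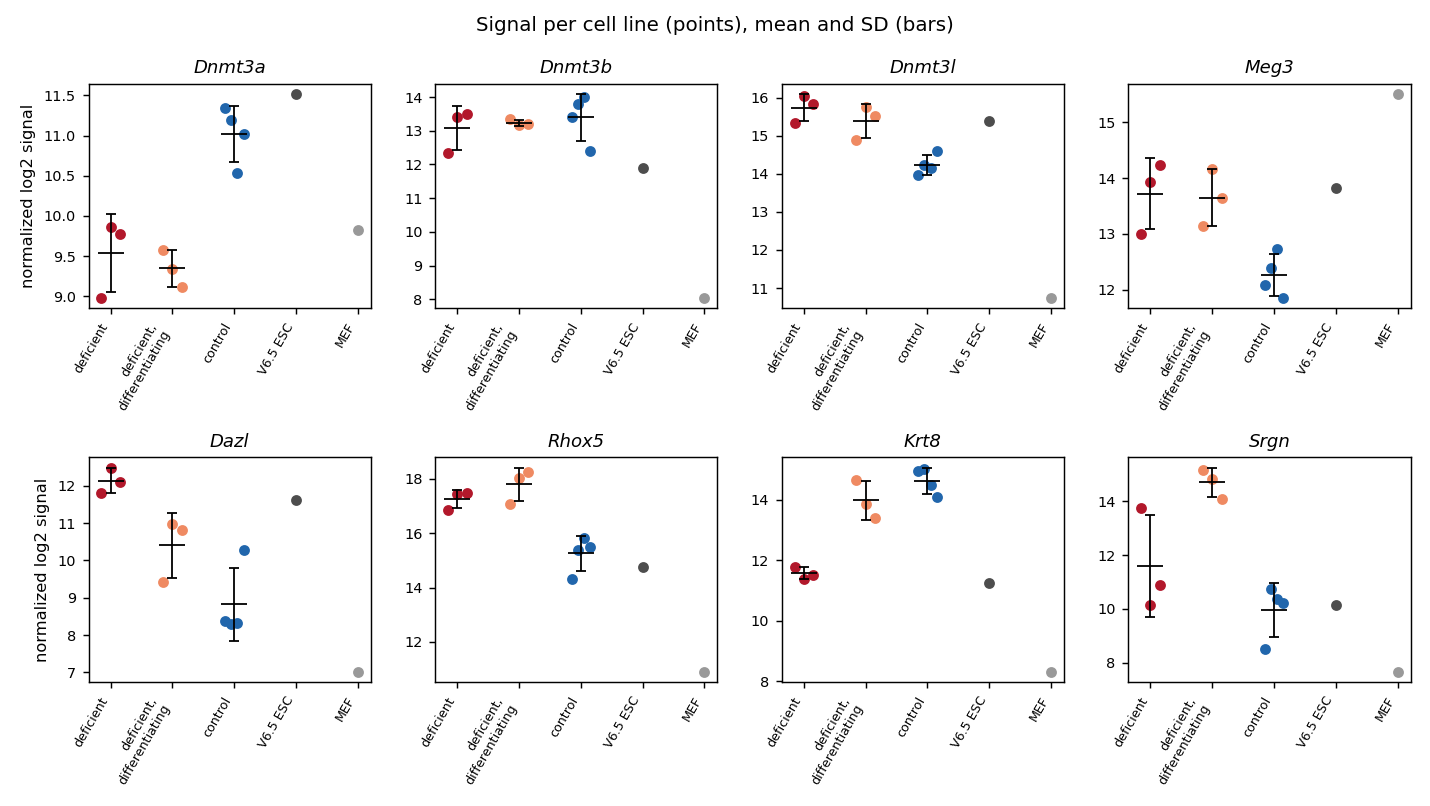
Normalized log2 signal of 8 genes in each cell line, by kind of RNA; points are lines, bars the mean and SD (V6.5 ESC and MEF are single RNAs). Dnmt3a was at 9.54 in deficient and 11.02 in control lines, and Dazl in control line 6 lay 1.95 above the mean of the other 3 control lines.

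Pou5f1, Sox2 and Nanog, transcription factors of the pluripotency network, were higher in the deficient iPSC. Pou5f1, which encodes Oct4, rose by 0.29 ± 0.0793 (adjusted p = 0.0249), Sox2 by 0.72 ± 0.103 (adjusted p = 0.00186) and Nanog by 1.05 ± 0.203 (adjusted p = 0.00621). Of 42 measured members of the core and naive pluripotency list, 11 were higher, 2 lower and 29 did not pass, and Dppa4 rose by 0.88 ± 0.124. Of 13 called members, 13 differed from control lines in the same direction in V6.5 ESC, also read on the first scan day. Their median difference was 0.66 there and 0.53 in deficient iPSC, though the same control values had chosen the genes. These changes can therefore not be assigned to deficiency rather than to scan day or a shared state. The list's adjusted camera p was 0.000314, and 0.504 with an estimated correlation; without normalization between arrays it pointed down (adjusted p = 0.144). Of 29 cell cycle genes of the G2 and M phases, 8 rose and 0 fell, led by Top2a, a DNA topoisomerase, at 1.11 ± 0.0632, and Bub1b, a spindle checkpoint kinase, at 0.54 ± 0.155 (list adjusted p = 0.000628; adjusted p = 0.504 with an estimated correlation).

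Germline genes, many of which are silenced by promoter methylation in somatic cells, were higher as a group. Of 64 measured, 31 rose, 8 fell and 25 did not pass (34 and 9 called adjusted over the list alone). Besides Dazl, 1700013H16Rik rose by 3.55 ± 0.747, Piwil4, a protein of the piRNA pathway, by 1.96 ± 0.169 and Fkbp6, a meiotic chaperone, by 1.93 ± 0.282. The list's adjusted p was 4.5e-07, and 0.527 with an estimated correlation. Of 39 called germline genes, 38 differed from control lines in the same direction in V6.5 ESC, also read on the first scan day. Their median difference was 0.74 there and 1.06 in deficient iPSC, though the same control values had chosen the genes. The rise can therefore not be assigned to deficiency rather than to scan day or a state shared by both kinds of cell. Of 22 measured genes of the X-linked Magea, Rhox and Xlr families, 9 rose and 0 fell, with Rhox5, a homeobox gene, at 1.99 ± 0.362 (list adjusted p = 2.08e-05; adjusted p = 0.504 with an estimated correlation). Of 19 genes typical of the 2-cell embryo, 10 rose and 0 fell, with Usp17la at 2.35 ± 0.72 (list adjusted p = 0.000336; adjusted p = 0.669 with an estimated correlation); which of its near-identical copies the probe reads is uncertain. Control line 6 stood apart from the other 3 control lines in each of these 3 groups, higher by a mean of 0.63, 1.12 and 1.19 log2 units respectively.

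Imprinted genes moved in both directions. H19, a maternally expressed noncoding RNA, rose by 2.05 ± 0.0808, its neighbour Igf2, a growth factor expressed from the paternal copy, by 1.51 ± 0.208 and Peg3, a paternally expressed zinc finger gene, by 1.08 ± 0.207, while Dcn, which is also a fibroblast proteoglycan, fell by 1.70 ± 0.225. Of 33 maternally expressed genes 7 rose and 8 fell (list adjusted p = 0.334), and of 35 paternally expressed genes 6 rose and 6 fell (list adjusted p = 0.298). Meg3, Rian and Mirg, the maternal noncoding RNAs of the Dlk1-Dio3 region, rose by 1.46 ± 0.332, 1.62 ± 0.325 and 1.07 ± 0.299, all 3 measured members of their list (list adjusted p = 0.034; adjusted p = 0.546 with an estimated correlation). Without clone B2 and without control line 6 that list's adjusted p was 0.0513 and 0.0694. H19 was also higher in V6.5 ESC, at 11.34, than in control lines, at 10.38 to 10.52, which were read on the other scan day.

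Fibroblast and feeder genes were lower in the deficient iPSC: of 46 measured, 28 fell, 3 rose and 15 did not pass. S100a4, a calcium-binding protein, fell by 2.28 ± 0.23 and Col1a1, a fibrillar collagen, by 1.96 ± 0.272 (list adjusted p = 0.00114; adjusted p = 0.726 with an estimated correlation). A second Col1a1 probe went the other way, at 0.41. In MEF, Col1a1 was at 18.40 ± 0.0862 (SD over 3 arrays). Of 31 called fibroblast genes, 31 differed from control lines in the same direction in V6.5 ESC. The median difference was 1.21 there and 0.83 in deficient iPSC. So did 8 of 8 called G2 and M phase, 10 of 10 2-cell stage, 8 of 9 X-linked family, 10 of 11 DNA methylation and 3 of 3 Dlk1-Dio3 genes. The same control values had chosen the genes, and these list results cannot be assigned to deficiency rather than to scan day or a shared state. Of 27 DNA methylation genes 8 rose and 3 fell (list adjusted p = 0.0252; adjusted p = 0.504 with an estimated correlation), and this list lost its call without clone B2 (0.0523) and without control line 6 (0.0694) and turned direction without normalization between arrays (0.437).

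The 12 lists not called in this comparison included markers of lineages. Among 22 primed and epiblast genes 4 rose and 7 fell, with Fgf8, a signalling factor of the epiblast, at -2.35 ± 0.443 and Sfrp2, a Wnt inhibitor, at -1.34 ± 0.144 (list adjusted p = 0.991, where the test pointed up and the median was -0.23). Among 34 endoderm genes 3 rose and 10 fell, with Thbd at -1.08 ± 0.331 (0.969; the median was -0.13 and the mean 0.02). Among 30 mesoderm genes 2 rose and 7 fell, with T at -0.81 ± 0.152 and Wnt3 at -1.13 ± 0.161 (0.969; the test pointed up with a negative median). The Wnt3 probe was well above background in 2 of 6 deficient channels, so the size of that difference depends on the background. Among 31 ectoderm and neural genes 6 rose and 12 fell, with Pax6 at 1.08 ± 0.244 and Zic2 at 0.97 ± 0.0981 (0.596). Among 35 trophoblast genes, which include Krt8 and Krt18, 2 rose and 11 fell (0.969), and among 37 Hox genes 3 rose and 14 fell, with Hoxc5 at -1.0 ± 0.0338 and Hoxc9 at -0.85 ± 0.0532 (0.208). Of 40 interferon response genes 5 rose and 8 fell, with Psmb8, an immunoproteasome subunit, at -1.66 ± 0.362 and H2-K1, a class I histocompatibility gene, at -1.41 ± 0.224 (0.969; the test pointed up with a negative median). Of 26 p53 targets 2 rose and 3 fell, with Plk2 at -0.92 ± 0.261 and Perp at -0.87 ± 0.186 (0.196). Of 17 X inactivation and Y-linked genes 0 rose and 4 fell, with Ftx at -0.64 ± 0.0411 and Kdm5d at -0.55 ± 0.155 (0.334), and of 29 housekeeping genes 4 rose and 8 fell, with B2m at -0.95 ± 0.115 and Gpi1 at -0.67 ± 0.126 (0.969; the test pointed up with a negative median). Kdm5d went to 0.01 without normalization between arrays. Hoxc5 and Ftx split by scan day in every kind of RNA. Hoxc5 was at 9.06 to 9.34 in deficient iPSC, V6.5 ESC and MEF, and at 10.14 to 10.33 in differentiating clones and control lines. For Ftx these ranges were 8.45 to 8.63 and 8.97 to 9.23. Their falls can therefore not be assigned to deficiency. Y-linked signal differed between lines within both groups. Eif2s3y was at 12.33 in clone 8 and at 8.48 and 8.10 in A6 and B2. In control line 6 it was at 7.93, and in control lines 3, 4 and 5 at 11.84 to 12.86.

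In total limma called 11629 of 25203 genes between deficient and control iPSC, 3838 higher and 7791 lower, and 426 of them differed by at least 1 log2 unit. Of 8098 genes with several probes, 612 had probes called in both directions, so the direction of a gene can depend on the probe. In the comparison of differentiating clones with control lines there were 4 such genes. That comparison called 4.89% of all genes, against 46.1% here, so fewer such genes were possible there. The median absolute difference over all genes was 0.197 with a median SE of 0.0653. The 3 and 4 lines did not overlap for 51.8% of genes, where chance gives 5.71%. Scan day and group cannot be told apart here: where genes were chosen with 2 control lines and without the arrays of V6.5 ESC, V6.5 ESC, read on the first day, differed from the other 2 control lines in the same direction for 88.8% to 95.9% of them over the 6 choices, and for 52.7% to 62% with permuted directions. Without normalization between arrays the median of all genes moved from -0.06 to 0.44 and 96.7% of 19605 called genes were higher, so the directions above are relative to equalized array distributions. In that setting fibroblast genes stayed called, while germline (0.684), X-linked family (0.144), 2-cell stage (0.802), Dlk1-Dio3 (0.802) and G2 and M phase genes (0.802) did not.

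The comparison of the differentiating deficient clones with the control lines was made within arrays. The largest rises were Srgn at 4.74 ± 0.563, Hkdc1 at 3.91 ± 0.397, Cubn at 3.80 ± 0.579, Ctsh at 3.05 ± 0.37, Hs3st1 at 3.02 ± 0.425 and Foxa2 at 2.66 ± 0.446 (n = 3 and 4 lines). Srgn is a secreted proteoglycan, Cubn an endocytic receptor of visceral endoderm, Ctsh a lysosomal protease and Foxa2 a transcription factor of endoderm. The largest falls were Fndc3c1 at -2.13 ± 0.354, Sp5 at -2.10 ± 0.238, Fgf8 at -2.09 ± 0.424, Ppp4r4 at -1.82 ± 0.303, Igfbp3 at -1.81 ± 0.238 and Cnn1 at -1.79 ± 0.172. Sp5 is a target of Wnt signalling and Cnn1 a contractile protein of smooth muscle and fibroblasts. Adjusted p-values of these 12 genes lay between 0.0242 and 0.0476.

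Endoderm genes rose as a group in the differentiating clones. Of 34 measured, 7 were higher, 0 lower and 27 did not pass, and 18 were higher when adjusted over the list alone. Gata6, a transcription factor of primitive endoderm, rose by 2.61 ± 0.345, Lama1, a basement membrane laminin, by 2.44 ± 0.315 and Sox17 by 1.52 ± 0.276, while Col4a1 at 2.10 ± 0.446 did not pass over all genes (adjusted p = 0.0507). The list's adjusted p was 1.22e-09, and 0.312 with an estimated correlation. The list's mean difference was 1.34, 1.03 and 0.82 within slides 3, 4 and 5, which hold clones 8, A6 and B2. Fibroblast and feeder genes fell: 12 of 46 were lower, 0 higher and 34 did not pass (34 lower and 2 higher adjusted over the list alone), with Col3a1 at -1.61 ± 0.288 (list adjusted p = 2.14e-15; adjusted p = 0.312 with an estimated correlation).

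Dnmt3a was again lower, by -1.68 ± 0.208 (adjusted p = 0.0254), Dnmt3l higher by 1.14 ± 0.235 (adjusted p = 0.0482), and Dnmt3b at -0.16 ± 0.364 and Dnmt1 at 0.21 ± 0.105 did not pass (adjusted p = 0.905 and 0.337). Pou5f1 at -0.12 ± 0.0783, Nanog at -0.54 ± 0.219 and Sox2 at 0.01 ± 0.13 did not pass either (adjusted p = 0.494, 0.228 and 0.991). Of 42 core and naive pluripotency genes 1 rose, 3 fell and 38 did not pass, with Lefty1, a Nodal inhibitor, at -1.14 ± 0.165 and Myc at -0.82 ± 0.16. That list's adjusted p was 0.00716, and 0.484 with an estimated correlation, and its call ended without clone 8 (0.229) and without control line 6 (0.177). Of 22 primed and epiblast genes 4 fell and 1, Foxa2, rose (list adjusted p = 0.000817; adjusted p = 0.312 with an estimated correlation). Of 27 DNA methylation genes 1 rose and 2 fell (list adjusted p = 0.497).

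Of 64 germline genes 5 rose and 1 fell (9 and 2 adjusted over the list alone), with Fkbp6 at 1.92 ± 0.336 and Piwil4 at 1.43 ± 0.284, while Dazl at 1.59 ± 0.622 did not pass (adjusted p = 0.21). The list's adjusted p was 0.000246, and 0.484 with an estimated correlation. Of 22 X-linked Magea, Rhox and Xlr genes only Rhox5 rose, by 2.52 ± 0.425, and 6 rose adjusted over the list alone (list adjusted p = 8.4e-05; adjusted p = 0.312 with an estimated correlation). Of 19 2-cell stage genes 1 rose, Zfp560 at 0.69 ± 0.145 (list adjusted p = 0.224). Mirg rose by 1.58 ± 0.237, while Meg3 at 1.39 ± 0.295 and Rian at 1.59 ± 0.34 did not pass over all genes, and all 3 passed adjusted over the list alone (list adjusted p = 0.000817; adjusted p = 0.312 with an estimated correlation). Of 33 maternally expressed imprinted genes 5 rose and 1 fell, with Slc22a18 at 0.89 ± 0.14 (list adjusted p = 0.0338; adjusted p = 0.428 with an estimated correlation), a call that ended without control line 6 (0.187), with slide as a block (0.0533) and with the mean of all probes (0.22). None of 35 paternally expressed genes passed (0.497).

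Of the other lists, 29 G2 and M phase genes had 4 higher and 0 lower, with Nusap1 at 0.53 ± 0.103 and Aurka at 0.36 ± 0.0639 (list adjusted p = 0.000175; adjusted p = 0.312 with an estimated correlation). Of 26 p53 targets 1 rose and 2 fell, with Tnfrsf10b, a death receptor, at 0.84 ± 0.143 and Perp at -1.71 ± 0.257 (list adjusted p = 0.00206, upward; adjusted p = 0.312 with an estimated correlation). Of 40 interferon response genes 0 rose and 5 fell, with Psmb8 at -1.76 ± 0.304 and Gbp2, an interferon-induced GTPase, at -1.53 ± 0.199 (list adjusted p = 0.00433; adjusted p = 0.484 with an estimated correlation; 0.086 without clone 8). Of 37 Hox genes only Hoxb2 fell, by 0.52 ± 0.0698 (list adjusted p = 0.00618; adjusted p = 0.312 with an estimated correlation). The remaining lists were not called: 30 mesoderm genes with 3 lower, Wnt3 at -1.23 ± 0.149 and Bmp4 at -0.76 ± 0.149 among them (0.199), 31 ectoderm and neural genes with Lhx2 at 0.80 ± 0.133 and Nes at -0.73 ± 0.0862 (0.708), and 35 trophoblast genes with Cdkn1c at 0.52 ± 0.0967 and Bmp8b at -0.78 ± 0.16 (0.18). No member of the 17 X inactivation and Y-linked genes (0.108) or of the 29 housekeeping genes (0.18) passed. For ectoderm and neural genes and for paternally expressed imprinted genes the mean, 0.02 and 0.01, lay above 0 while the median and the test pointed down.

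**Figure D2:**
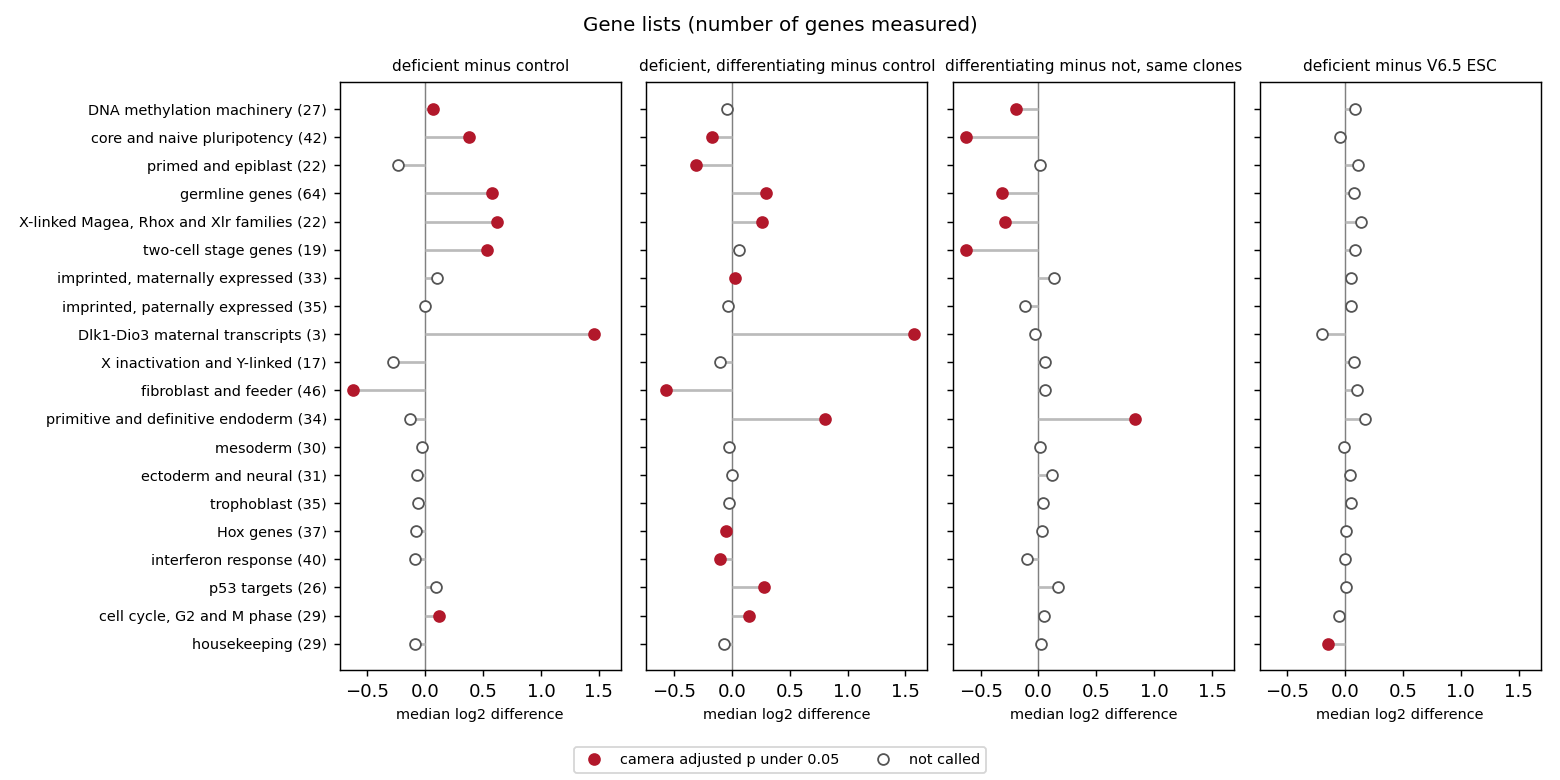
Median log2 difference of each of the 20 gene lists in 4 comparisons; filled points have an adjusted camera p under 0.05 at the preset correlation. Endoderm genes had a median of 0.80 in differentiating clones against control lines; with an estimated correlation only the housekeeping list against V6.5 ESC (adjusted p = 0.00756) passed among those drawn.

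In this within-array comparison limma called 1232 genes, 584 higher and 648 lower, 185 of them by at least 1 log2 unit, and 5258 had an unadjusted p under 0.05. Lines did not overlap for 19.4% of genes, where chance gives 5.71%. The count depended on single lines: it was 0 without clone A6, without clone B2 or without control line 3, 27 without control line 4 and 3474 without control line 6. Within slides 3, 4 and 5 it was 0, 3939 and 5236, and with slide as a block 4831; each slide holds 1 deficient clone, so the counts within slides have 4 arrays as replicates and carry the deviation of that clone.

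The same 3 clones with and without signs of differentiation were compared as pairs, across scan days. Genes higher with differentiation were led by Hkdc1 at 3.69 ± 0.416, Clu at 3.28 ± 0.181, Ctsh at 3.22 ± 0.302, Slco2a1 at 3.15 ± 0.225, Srgn at 3.12 ± 0.655 and Foxa2 at 2.85 ± 0.301 (log2 difference ± SE, n = 3 pairs). Clu is a secreted chaperone and Slco2a1 a prostaglandin transporter. The largest falls were Calcoco2 at -2.39 ± 0.164, Igf2 at -2.18 ± 0.0949, Sltm at -2.10 ± 0.0781, Malat1, a nuclear noncoding RNA, at -2.0 ± 0.266, Zscan4c at -1.96 ± 0.296 and Sycp1-ps1 at -1.86 ± 0.0516. Malat1 was at 12.4 to 14.95 in all RNA of the first scan day and at 10.23 to 11.3 in that of the second. Within arrays it did not differ between differentiating clones and control lines (-0.1, limma adjusted p = 0.929). Its fall can therefore not be assigned to differentiation. Nanog fell by 1.59 ± 0.143, Sox2 by 0.71 ± 0.142 and Pou5f1 by 0.40 ± 0.0457 (adjusted p = 0.00444, 0.019 and 0.00595). Dnmt3l fell by 0.36 ± 0.0508 and Dnmt1 by 0.41 ± 0.067 (adjusted p = 0.00888 and 0.0121), while Dnmt3a at -0.19 ± 0.277 and Dnmt3b at 0.15 ± 0.297 did not pass (adjusted p = 0.588 and 0.685).

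Of 34 endoderm genes 28 rose, 1 fell and 5 did not pass, with Lama1 at 2.22 ± 0.218, Col4a1, a basement membrane collagen, at 2.20 ± 0.173 and Gata6 at 2.02 ± 0.214 (list adjusted p = 3.07e-05; adjusted p = 0.63 with an estimated correlation). Of 42 core and naive pluripotency genes 26 fell and 1 rose, with Tbx3 at -1.13 ± 0.229 (1.32e-07; adjusted p = 0.85 with an estimated correlation). Of 64 germline genes 28 fell and 7 rose, with Dazl at -1.73 ± 0.245 and 1700013H16Rik at -1.58 ± 0.399 (3.07e-05; adjusted p = 0.63 with an estimated correlation). Of 22 X-linked family genes 8 fell and 2 rose, with Mageb4 at -0.77 ± 0.0888 and Rhox9 at -0.67 ± 0.156 (0.00244; adjusted p = 0.892 with an estimated correlation), and of 19 2-cell stage genes 12 fell and 0 rose (1.69e-05; adjusted p = 0.892 with an estimated correlation). Of 27 DNA methylation genes 10 fell and 4 rose, with Mbd3, a methyl-binding domain protein, at -0.97 ± 0.0687 and Trim28, a corepressor, at -0.93 ± 0.0886 (0.00697; adjusted p = 0.63 with an estimated correlation); this list pointed up without normalization between arrays (0.858).

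The other 14 lists were not called. Krt8 rose by 2.41 ± 0.204 among 35 trophoblast genes with 11 higher and 8 lower (0.596), and S100a4 by 1.53 ± 0.131 and Sparc by 1.44 ± 0.161 among 46 fibroblast genes with 10 higher and 10 lower (0.428). H19 fell by 1.79 ± 0.0808 and Dhcr7, an enzyme of cholesterol synthesis, rose by 1.44 ± 0.0413 among 33 maternally expressed genes with 13 higher and 2 lower (0.747), and Ddc fell by 1.02 ± 0.0901 among 35 paternally expressed genes with 6 higher and 8 lower (0.058). Mirg rose by 0.51 ± 0.13 while Meg3 and Rian did not pass (0.989). Among 22 primed and epiblast genes 7 rose and 9 fell, with Fgf5 at -1.18 ± 0.294 (0.428), among 30 mesoderm genes 10 rose and 7 fell, with Pdgfra at 1.62 ± 0.0836 and Msx2 at 0.95 ± 0.146 (0.842), and among 31 ectoderm and neural genes 13 rose and 4 fell, with Sox11 at 1.51 ± 0.0991 and Zic2 at -1.16 ± 0.156 (0.428). Among 37 Hox genes 11 rose and 7 fell, with Hoxa7 at -0.92 ± 0.0448 and Hoxc5 at 0.91 ± 0.053 (0.989). Interferon response genes split 7 and 7 of 40, with H2-K1 at 1.44 ± 0.2 and Irgm1 at -1.38 ± 0.198 (0.272), p53 targets 6 and 2 of 26, with Bbc3 at 0.92 ± 0.11 and Tnfrsf10b at 0.83 ± 0.0933 (0.962), and G2 and M phase genes 4 and 7 of 29, with Top2a at -0.81 ± 0.0843 and Prc1 at 0.56 ± 0.08 (0.428). X inactivation and Y-linked genes had 5 higher and 2 lower of 17, with Rlim at 0.76 ± 0.211 and Ftx at 0.61 ± 0.0582 (0.989), and housekeeping genes 7 and 7 of 29, with Actb at -0.61 ± 0.144 (0.596). Hoxc5 and Ftx split by scan day in every kind of RNA, as given above. H19 was at 11.34 to 14.99 in all RNA of the first day and at 10.38 to 10.75 in that of the second. The changes of these genes can therefore not be assigned to differentiation. The test pointed down with a positive median and mean for the fibroblast, mesoderm, trophoblast, Hox, X inactivation and housekeeping lists. It pointed down with medians of 0.02 and 0.04 and negative means for primed and for G2 and M phase genes, and with a median of -0.03 and a mean of 0.13 for the Dlk1-Dio3 list.

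Between the states limma called 13176 genes, 8319 higher and 4857 lower with differentiation, 394 of them by at least 1 log2 unit, and all 3 pairs had 1 sign for 75.7% of genes, where chance gives 25%. The states were read on different scan days and cannot be told apart from them. The count was 0 without clone A6 and 6955 without clone B2, and without normalization between arrays only 4.99% of 20619 called genes were higher, with the median of all genes at -0.44. In that setting endoderm genes stayed called, and core pluripotency (0.667), germline (0.294), X-linked family (0.552) and 2-cell stage genes (0.152) did not.

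Against V6.5 ESC the largest rises in deficient iPSC were Serpina3m, a serine protease inhibitor, at 2.43 ± 0.609, Rhox5 at 2.41 ± 0.534, Spink2 at 2.00 ± 0.46 and Lefty2, a Nodal inhibitor, at 1.83 ± 0.295 (n = 3 arrays). The largest falls were Zfp42, also called Rex1, a marker of naive pluripotency, at -2.61 ± 0.212, Dnmt3a at -1.90 ± 0.369, Ly75 at -1.86 ± 0.243 and Kbtbd11 at -1.85 ± 0.367. Pou5f1, Nanog, Sox2, Dnmt1, Dnmt3b and Dnmt3l did not pass. Of 42 core and naive pluripotency genes 4 rose and 5 fell (list adjusted p = 0.332). Of 33 maternally expressed imprinted genes 6 rose and 1 fell, with Grb10, a growth-restricting adaptor, at 1.60 ± 0.351 and Cdkn1c, a cyclin-dependent kinase inhibitor, at 0.76 ± 0.167 (0.706), and Peg3 rose by 1.60 ± 0.295 and Ddc by 0.68 ± 0.134 among 35 paternally expressed genes with 0 lower (0.642). Meg3 at -0.20 ± 0.407 and Rian at -0.34 ± 0.514 did not pass.

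Of 29 housekeeping genes 8 were lower than in V6.5 ESC and 2 higher (list adjusted p = 5.34e-06; adjusted p = 0.00756 with an estimated correlation), a call that ended with the scanner's processed signals (0.471). The other 19 lists were not called. Of 64 germline genes 2 rose, among them Syce1, a synaptonemal complex protein, at 1.52 ± 0.207 (0.976), of 22 X-linked family genes 1, Rhox5 (0.0972), and of 22 primed and epiblast genes 1, Lef1, at 1.52 ± 0.409 (0.383). Tubb3 rose by 1.00 ± 0.17 (ectoderm and neural, 0.697), Msx1 by 0.13 ± 0.0343 (mesoderm, 0.562), Tfap2a by 0.16 ± 0.0398 (trophoblast, 0.976) and Hoxc4 by 0.16 ± 0.0447 (Hox, 0.836), and Trf fell by 0.45 ± 0.107 (endoderm, 0.574). Hoxc5 was at 0.34 ± 0.0648 with the dye term and at -0.11 without it. Counts of 0 or 1 called gene were found in the DNA methylation (0.562), X inactivation and Y-linked (0.562), fibroblast (0.8), interferon (0.642), p53 (0.562), Dlk1-Dio3 (0.715) and 2-cell (0.902) lists, and G2 and M phase genes split 3 and 3 (0.294). For Hox and interferon genes the test pointed down with a positive median and mean, and for p53 targets the median was 0.01 and the mean -0.03.

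In total limma called 1340 genes against V6.5 ESC, 874 higher and 466 lower, 77 of them by at least 1 log2 unit. The direction of the surplus depended on the processing: 65.2% were higher here, 45% of 3504 with the scanner's processed signals and 41.7% of 3720 in the deposited value table. The count fell to 382 without clone B2 and 439 without clone A6, and the single V6.5 RNA adds calls of its own deviation.

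Against MEF the deficient iPSC showed the contrast of pluripotent and somatic cells. Sox2 was higher by 7.10 ± 0.156, Dppa5a, an RNA-binding protein of pluripotent cells, by 6.79 ± 0.204, Mycn by 6.62 ± 0.157, Smc1b, a meiotic cohesin, by 6.58 ± 0.795, Nanog by 4.28 ± 0.303 and Pou5f1 by 4.11 ± 0.0912 (n = 3 arrays). The largest falls were Col1a1 at -6.25 ± 0.309, Fibin at -6.13 ± 0.426, Aspn at -6.05 ± 0.15 and Itga11, a collagen receptor, at -5.76 ± 0.246. Aspn was well above background in 0 of 6 deficient channels, so its fitted change depends on the background, against which MEF signal was at least 49.6-fold higher. Dnmt3l was higher by 5.08 ± 0.284, Dnmt3b by 5.05 ± 0.423 and Dnmt1 by 1.25 ± 0.119, while Dnmt3a at -0.36 ± 0.369 did not pass (adjusted p = 0.429).

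Of 42 core and naive pluripotency genes 38 were higher than in MEF and 3 lower (list adjusted p = 1.16e-17; adjusted p = 0.0385 with an estimated correlation), all 29 G2 and M phase genes were higher (1.31e-16; adjusted p = 0.00183 with an estimated correlation), and 30 of 37 Hox genes were lower and 2 higher (4.22e-12; adjusted p = 0.00183 with an estimated correlation). All 46 fibroblast genes were lower (9.98e-21; adjusted p = 0.134 with an estimated correlation), and 50 of 64 germline genes were higher and 4 lower (7.52e-09; adjusted p = 0.242 with an estimated correlation). Primed and epiblast genes (11 higher, 3 lower of 22; 0.0125, and adjusted p = 0.293 with an estimated correlation), X-linked family genes (15 and 2 of 22; 0.0142, and adjusted p = 0.5 with an estimated correlation), maternally expressed imprinted genes (8 and 20 of 33; 0.0125, and adjusted p = 0.293 with an estimated correlation) and mesoderm genes (4 and 16 of 30; 0.0278, and adjusted p = 0.236 with an estimated correlation) were called as well. The other 11 lists were not called, with adjusted p from 0.0564 for 2-cell stage genes to 0.961 for endoderm, paternally expressed and X inactivation genes; endoderm genes had a positive median and a negative mean, and for X inactivation and Y-linked genes the test pointed down with a positive median and mean. limma called 14645 genes, 7082 higher and 7563 lower, 5965 of them by at least 1 log2 unit, and the single MEF RNA adds calls of its own deviation.

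The comparison of the differentiating clones with control lines and that of deficient iPSC with V6.5 ESC were each made within arrays, but with the same 3 clones and the same dye estimate, so the lists are not independent. They had 30 higher and 16 lower genes in common, where independent lists would give 20.3 and 12 (one-sided Fisher's exact p = 0.0217 and 0.149, same exact test), and 26 and 49 genes went in opposite directions, where they would give 10.8 and 22.5. These expected numbers and p-values assume independence, so no conclusion is drawn from them. Rhox5 was higher in both, at 2.52 and 2.41, and so were H19 at 0.25 and 0.69 and Cdkn1c at 0.52 and 0.76. Dnmt3a was lower in both, at -1.68 and -1.90, and so were Itm2a at -0.91 and -1.18 and Igfbp2 at -0.42 and -1.23.

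No chromosome was called by camera between deficient or differentiating clones and control lines (0 of 21 in each). Genes of chromosome 8 lay above the median of the 10 line-and-state values in clone 8 in both states, by 0.162 and 0.14, where the next of the autosomes and X of that clone was at -0.015 and 0.01. Among autosomes and X, chromosome 8 was also the highest in control line 3, at 0.058 (next 0.014), and lay at -0.078 in control line 4 and -0.073 in clone B2 without signs of differentiation. Chromosome 3 genes lay at 0.09 and 0.101 in clone B2 in the 2 states, and X-linked genes at 0.193 in control line 6.

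**Figure D3:**
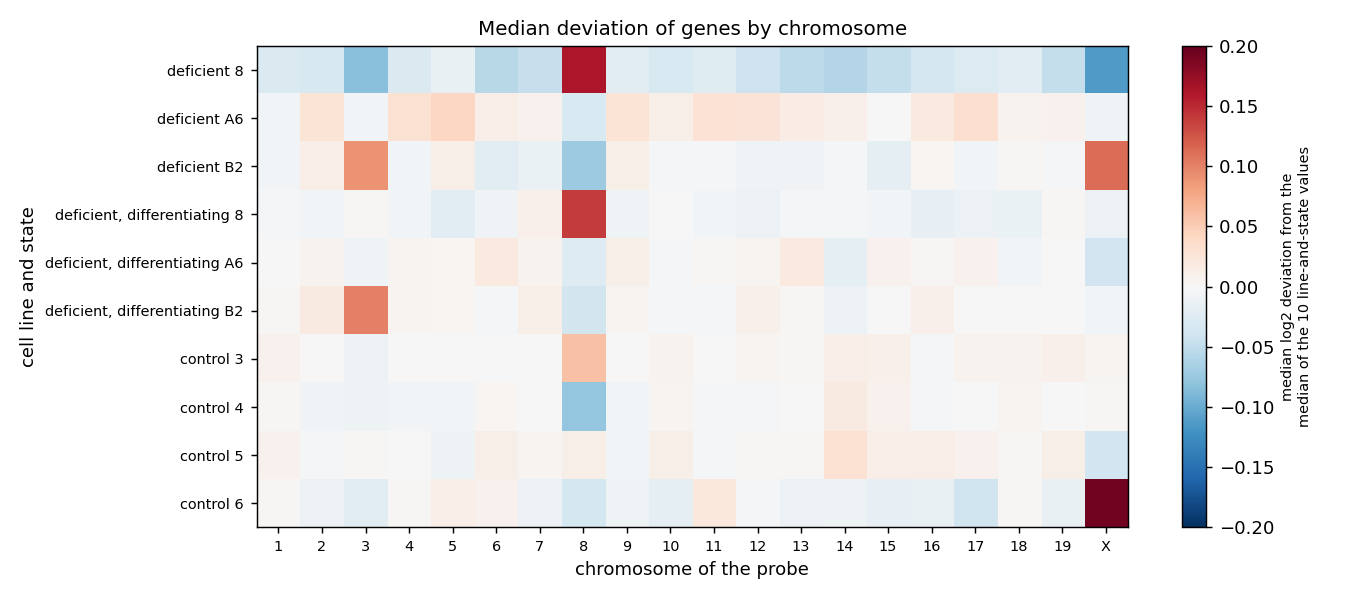
Median log2 deviation of genes on each chromosome from the median of the 10 line-and-state values, for genes above the median signal. Chromosome 8 in clone 8 (0.162 and 0.14) and X in control line 6 (0.193) were the highest values among autosomes and X in those lines.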

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

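The tests on V6.5 ESC and MEF values, on control line 6 and on the chromosome 8 shift across scan days were chosen after the results had been seen. The splits of the lines were set beforehand. The test by parts of chromosome 8 was set before its own result, but it addressed a shift in clone 8 that was already known.

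Many more genes differed between deficient and control iPSC, read on different scan days, than between differentiating clones and control lines, read within arrays (11629 against 1232). Genes and directions were chosen on deficient channels from arrays without the reference RNA and on 2 control lines, and the differences from the other 2 control lines were then compared, over 6 choices of lines. The V6.5 minus control difference was 0.98 to 1.06 of the deficient one (0.16 to 0.61 with 100 permutations of the directions), which argues against loss of Dnmt3a and Dnmt3b as the source of most of these calls, since V6.5 ESC kept a Dnmt3a signal of 11.52, though its Dnmt3b, at 11.9, lay below all deficient and control lines (12.34 to 13.99); the differentiating clones, deficient too, had -0.09 to 0.05 on these genes. For MEF, also read on the first day, the ratio was -0.02 to 0.25 (permuted -0.21 to 0.22), which argues against a shift common to all RNA of that day as the whole of the pattern. Over all 11629 called genes, MEF differed from control lines in the direction of the call for 69.1%. The median there was 0.18 in MEF against 0.33 in deficient iPSC, but the same control values had also chosen those genes. An effect of scan day on part of the genes or on some kinds of RNA, and a state of the cells shared by deficient iPSC and V6.5 ESC, cannot be told apart, since control lines were read on the second day only.

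Whether the grouping of lines could arise by chance was tested with other splits of the 7 lines into 3 and 4. For deficient against control iPSC 1 of 35 splits, the real one, gave as many genes, and the highest of the others was 2436. For differentiating clones against control lines it was also 1 of 35, with 774 as the highest other. Both shares lie under 0.05, and 1 of 35 is the smallest share that these splits allow. The splits treat the lines as exchangeable. For deficient against control iPSC the real split is also the split by scan day, so its rank cannot tell group from day. For differentiating clones against control lines the count of 1232 was 0 without clone A6, without clone B2 or without control line 3. In both comparisons the highest other split set control lines 3, 4 and 5 against the rest, which places control line 6 with the deficient clones and points to a structure of the samples. The only further split with any calls set A6, B2 and control line 6 against the others, with 84 and 29 genes. Y-linked Eif2s3y was at 7.93 to 8.48 in these lines, without signs of differentiation, and at 11.84 to 12.86 in clone 8 and control lines 3, 4 and 5. Y-linked signal was thus not balanced between the groups. For the paired comparison there are 4 sign patterns, too few for a share under 0.05; the real one gave 13176 genes and the highest of the others 0, so 1 of 4, the real one, gave as many.

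Control line 6 lay far from the other 3 control lines in 15 of 149 values tested, and control line 5 in 3, where chance gives about 1 in 20 groups. In log2 units its differences from their mean were 2.86 for 1700013H16Rik, 2.56 for Usp17la, 2.53 for Zscan4c, 2.13 for Rhox9, 1.97 for Hormad1, 1.95 for Dazl, 1.74 for Mageb4 and 0.49 for Pttg1. It was lower for Grb10 (-1.13), Kbtbd11 (-1.01), Kdm5d (-0.44) and Cdkn1c (-0.25). The means of germline genes, X-linked Magea, Rhox and Xlr families and 2-cell stage genes lay higher by 0.63, 1.12 and 1.19. Control line 5 was lower for Myc (-0.49), Trim28 (-0.3) and Hoxb2 (-0.18). The 149 values are not independent, since genes of a list can move together and also enter its mean. The 15 flagged values are therefore not separate results, and their number cannot be judged against the chance rate.

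Deficient RNA in the place of the control line 6 sample is spoken against by Dnmt3a, since that line lay nearer to the other control lines than to the deficient ones at 3 of 3 probes. The median of X-linked genes in control line 6 was 0.193, above that of every autosome of the line (next 0.021), and its Y-linked Eif2s3y was at 7.93 where control lines 3, 4 and 5 were at 11.84 to 12.86. A higher dosage of X-linked genes is consistent with the median of 0.193 and may underlie part of the X-linked families, but whether it acts on autosomal genes such as Dazl and Zscan4c was not tested. Dnmt3b was at 12.41 in this line and at 13.40 to 13.99 in the other control lines, and the state of the cells stays open.

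Chromosome 8 genes lay higher in clone 8. Their median lay above those of all other autosomes and X in clone 8 on 2 of 2 scan days, as already seen when the test was chosen, which argues against an effect of the arrays of 1 day alone. Chromosome 8 also varied between other lines, at 0.058 in control line 3, -0.078 in control line 4 and -0.073 in clone B2. Between 62.4% and 80.1% of the genes lay above 0 in each of 3 equal parts of the chromosome, by gene order, in both states. The lowest, 62.4, was near the bound of 60, which was set before these shares were seen. The same genes had given the medians above 0, so it was already known that most of them lay above 0. A whole extra chromosome 8 in part or all of the cells is a candidate explanation that passed this test. The test did not weigh the size of the shift, so it cannot tell part of the cells from all of them. Any small shift along the whole chromosome would also pass it, so it does not show a change in copy number. As deficiency was not varied within a clone, no other biological explanation was tested.

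The 2 states of the deficient clones, read on different scan days, differed from each other in 13176 genes by the paired limma test. The count was 0 without clone A6. Of the called genes 63.1% were higher with differentiation, and 4.99% without normalization between arrays. For the called genes the difference from control lines differed between the 2 sets of samples, but it cannot be assigned to state rather than to scan day.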

How the results depend on the processing

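Alternatives by slide, and those leaving out control line 6 and clone 8 together, were chosen after seeing the data; all other alternatives were set beforehand. The planned fit with slide as a fixed block was not run for deficient against control iPSC, since no slide held both groups. Signal over background differed between scan days, which limits the comparisons across them, and the cause of the changes below was not tested except where stated.

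With a change of at least 1 log2 unit required, fewer genes passed by construction: 426, 185, 394, 77 and 5965 in the order deficient against control, differentiating against control, differentiating against not, against V6.5 ESC and against MEF. Without normalization between arrays deficient against control gave 19605 genes and differentiating against not 20619, with medians of all genes at 0.44 and -0.44; with the scanner's processed signals these medians were -0.11 and 0.12. Against V6.5 ESC the scanner's processed signals gave 3504 genes and the deposited log ratios 3720. Differentiating against control gave 8014 genes with the 12 arrays as replicates, 4831 with slide as a block, 4986 without control line 6 and clone 8, and 0, 3939 and 5236 within slides 3, 4 and 5, each of which holds 1 deficient clone on 4 arrays; the count of 0 from limma had 5314 genes at an unadjusted p under 0.05. With an estimated correlation the called lists went from 8, 12, 6 and 9 to 0, 0, 0 and 3, the last 2 numbers of each being between states and against MEF; the 1 list called against V6.5 ESC stayed called.

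Leaving out 1 line at a time gave 8837 to 13812 genes for deficient against control, 0 to 3474 for differentiating against control, 0 to 14573 between states, 382 to 1429 against V6.5 ESC and 13068 to 13679 against MEF. Called lists ranged from 6 to 8, 11 to 13 and 6 to 8 in the first 3 comparisons, and called chromosomes from 0 to 0. The count for differentiating against control was 0 without A6, B2 or control line 3, 27 without control line 4 and 3474 without control line 6. Between states it was 0 without A6 and 6955 without B2, and against V6.5 ESC 439 without A6 and 382 without B2.

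Over all genes, directions depended on normalization between arrays. For deficient against control 33% of called genes were higher with it and 96.7% without it. Between states these shares were 63.1% and 4.99%. Among the named genes, few turned direction. Without normalization between arrays Kdm5d was at 0.01 (deficient against control) and Dnmt3b at -0.17 (between states), and without a dye term Hoxc5 was at -0.11 against V6.5 ESC. With 1 line left out Dnmt3b ran from -0.64 to 0.06 (deficient against control, turning without clone 8), from -0.49 to 0.04 (differentiating against control, turning without control line 5) and from -0.27 to 0.39 (between states, turning without clone 8), and Dnmt3a between states from -0.58 to 0.04, turning without B2. Sox2 in differentiating against control was at 0.12 without clone 8, -0.11 without B2, -0.04 without control line 5, -0.02 without control line 6 and -0.2 within slide 3. Of 750 values of named genes under other settings for deficient against control, 728 kept their direction and side of the threshold, and 525 of 611, 419 of 450, 260 of 297 and 126 of 126 did in the other comparisons; with 1 line left out these were 319 of 350, 122 of 287, 95 of 150, 57 of 99 and 42 of 42.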

Other observations

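Values per line showed where single clones differed, and none of the differences between single lines in this part was tested. Among the deficient iPSC without signs of differentiation, clone 8 had a mean endoderm signal of 10.31 (34 genes), against 9.53 in A6 and 9.56 in B2, and control lines 3, 4 and 6 ran from 9.51 to 9.79, with control line 5 between those and clone 8. Srgn was at 13.73 in clone 8, 10.14 in A6 and 10.88 in B2, and with signs of differentiation at 15.16, 14.84 and 14.09. Krt8 was at 11.39 to 11.78 in deficient iPSC and 11.23 in V6.5 ESC, but at 13.40 to 14.66 in differentiating clones and 14.07 to 15.01 in control lines. Zfp42 was at 15.71 in V6.5 ESC and at 12.43 to 13.65 in the 10 iPSC line-and-state values.

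The maternal transcripts of the Dlk1-Dio3 region had a mean signal of 9.14 to 9.75 in the 4 control lines, 10.07 to 11.27 in deficient iPSC and 10.32 to 11.42 in the differentiating clones. V6.5 ESC were at 10.89 and MEF at 12.20. Eif2s3y, a Y-linked gene, was at 12.33 in clone 8 and at 8.48 and 8.10 in A6 and B2, and at 12.54, 8.35 and 7.92 in the same clones with signs of differentiation. V6.5 ESC were at 10.63 and MEF at 6.92. Chromosome 3 genes were higher in clone B2 in both states, at 0.09 and 0.101, and X-linked genes were at 0.111 in B2 without signs of differentiation and -0.006 with them.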
